A study of Arabidopsis thaliana with 9 samples.

How the data were processed

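Messenger RNA was sequenced from 10-day-old Arabidopsis seedlings of 3 genotypes: wild type (WT), arid2/3/4 and epcr1/2, with 3 libraries of each. The series title names the PEAT protein complexes, histone deacetylation and heterochromatin silencing. Per the labels, total RNA came from seedlings grown on plates in long days, and libraries were prepared for mRNA sequencing. The labels name STAR 2.5.2b, Cuffdiff and the TAIR10 genome build.

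The authors deposited 1 table of 28117 genes and 9 libraries. Its header names no unit. The deposited values were read as FPKM (fragments scaled by transcript length and by mapped fragments), inferred from their unequal column sums, their decimals and the steps on which the smallest values fall. No counts were used here, so no counting interval is given for any value. The steps of the smallest values, multiplied by transcript length, gave a rough estimate of 20.4 to 29.0 M fragments in the libraries numbered 1 and 2 and 55.6 to 64.5 M in those numbered 3. All 278 chloroplast and mitochondrial genes were listed at 0. The other 27839 genes were matched by locus tag to the TAIR10.1 annotation, which supplied names, transcript lengths and the order of genes only. That annotation marks 4851 pseudogenes, and 1 of them was in the table, so transposable element genes annotated as pseudogenes were not analysed here.

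Genes at 0.5 FPKM or more in at least 3 of the 9 libraries were tested, which left 21168. Values were analysed as log2(FPKM + 1), without further scaling, in 1 linear model with a mean per genotype (limma 3.58.1 in R 4.3.3, empirical Bayes with a trend of the variance on expression). P-values were adjusted by Benjamini-Hochberg over all tested genes of a comparison, and an adjusted p under 0.05 was called with no minimum fold. The pseudocount of 1 shrinks the fold of genes at low FPKM. The labels name no separate cultures, so the p-values measure the spread between these samples, which may be technical. Replicates 1 and 2 of a genotype were so alike (r of 0.994 to 0.995) that they may share plants. In that case n = 3, the SE and the p-values overstate the number of independent samples. With these 2 averaged and a batch block, 2003 genes in place of 4399 changed in arid2/3/4, and 4814 in place of 6039 in epcr1/2. Between the mutants 49 in place of 2218 differed. That fit has 2 residual degrees of freedom against 6, so part of each drop may come from fewer samples.

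The genotypes share replicate numbers in the labels. Deviations from the genotype means correlated across genes by 0.63 to 0.84 in all 9 pairs of libraries with the same number, above the limit of 0.1, which met the rule for running the replicate number as a block. Libraries numbered 1 and 2 of different genotypes and different numbers correlated as much, by 0.66 to 0.76, and those numbered 3 with the others by -0.82 to -0.68. The correlation therefore sets replicate 3 apart, and does not show that 1 pairs with 1 and 2 with 2. Without a block, the fit counts this shift as spread between samples, although its shared part cancels between genotypes. The fit with the replicate number as a block was run beside it, and its values stand beside the counts and calls that it changed.

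At the same stage as the comparisons and tests, 15 gene lists were written by hand with 280 entries, and 3 more were defined by annotation: transposable element genes, cytosolic ribosomal protein genes and core histone genes. An entry (BNS) was dropped because its symbol contradicts that in the annotation. The transposable element list follows words in a gene's name or description, so it also holds genes described as acting on transposons. It misses genes named only as a transposase. The ribosomal list follows its written rule and still holds RPL12-A and RPL12-C, described as 50S proteins, and RPL27, which its annotation places in the chloroplast. A planned list of pericentromeric genes was not run, because it depended on coordinates of the build the file used, and the file carries none. Lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over 18 lists and both mutants, and again with an estimated correlation. No list passed with the estimated correlation. A call lost there need not mean that the genes are correlated, as the floral list had an estimated correlation of -0.016, below the preset value.

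The genes named follow a rule fixed at the same time: the mutated genes and the other PEAT genes, the 10 largest rises and 10 largest falls in each mutant whose libraries do not overlap those of WT and whose higher mean is at least 1 FPKM, 5 in each direction between the mutants and shared by them, and up to 4 passing members of each list (2 where none passed). From these, the text shows a selection made after the alternatives were seen, which leans to genes whose calls held, and it names those whose calls ended. A gene under 2-fold fails a 2-fold minimum by construction, which is not repeated for each. Other genes, named as such, were chosen after their values were seen.

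The 3 comparisons were each mutant against WT and the mutants against each other. The overlap between the mutants was set beside 100 simulated data sets in which unchanged groups shared the WT libraries, and of 100 more, added after the data were seen, that also carried the shift of replicate 3. Alternatives chosen before the data were examined were a pseudocount of 0.1, no filter, a filter at 2 FPKM, centring on the median of genes at 5 FPKM or more, quantile normalization, robust empirical Bayes with array weights, a fit of only the groups compared, the replicate block, a minimum of 2-fold, and leaving out each library. After the data were seen, 5 were added: replicates 1 and 2 only, a batch term for the libraries numbered 3, replicates 1 and 2 averaged as 1 sample with a batch block, genes above 0 in all libraries, and transposable element genes by product name only.

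The method was tested on simulated data with the gene spreads of all 9 libraries. Of 100 genes changed 2-fold, 23 were called, and of 100 changed 4-fold, 60 were called, with 10 false calls. With the spread left after the replicate block, these were 49, 86 and 7. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used for tables, and matplotlib 3.10.9 for figures.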

Results

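The data were transcript levels of 28117 genes in 9 libraries of Arabidopsis seedlings: 3 of WT, 3 of arid2/3/4 (mutated in 3 genes with an ARID DNA-binding domain) and 3 of epcr1/2 (mutated in 2 genes of the Enhancer of Polycomb-related type). The approximate depth was 27.0, 23.3 and 55.7 M fragments in WT replicates 1, 2 and 3, 27.2, 23.2 and 64.5 M in arid2/3/4 and 29.0, 20.4 and 55.6 M in epcr1/2. Between 22490 and 24297 genes had a value above 0 in a library. The libraries numbered 1 and 2 of a genotype were nearly alike, with Pearson r of 0.994 to 0.995 across genes, and the library numbered 3 stood apart from both, with r of 0.835 to 0.883. At 100 to 200 FPKM the robust SD of log2 ratios was 0.082 to 0.136 between replicates 1 and 2, 0.701 to 0.896 between replicate 3 and another of its genotype, and 0.027 expected from counting alone. Genes are not independent replicates in these correlations.

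The mutated genes show what each mutant has lost at the transcript level. ARID2 was 21.7 ± 1.35 FPKM in WT and 2.11 ± 0.0428 in arid2/3/4 (mean ± SD, n = 3), a log2 fold change of -2.87 ± 0.12 (SE, limma adjusted p = 3.27e-05). ARID4 fell from 12 ± 1.47 to 3.66 ± 0.578 FPKM (-1.48 ± 0.15, limma adjusted p = 0.000769), and ARID3 from 8.52 ± 0.252 to 4.42 ± 1.06 FPKM (-0.83 ± 0.16, limma adjusted p = 0.00945). In epcr1/2, EPCR1 fell from 12.9 ± 3.11 to 0.646 ± 0.385 FPKM (-3.08 ± 0.24, limma adjusted p = 0.00019). EPCR2 was 8.36, 6.99 and 11.8 FPKM in WT and 10.1, 10.4 and 12 in epcr1/2 (0.27 ± 0.25, limma adjusted p = 0.474), and passed only with array weights and from replicates 1 and 2 only. A transcript level does not show whether a gene product is functional.

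**Figure D1:**
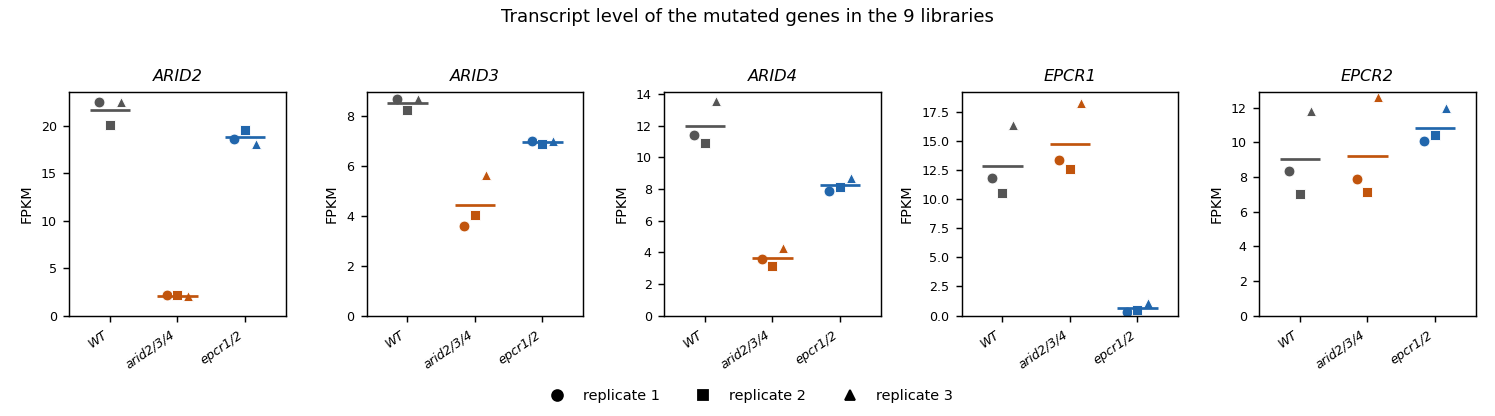
Transcript level in FPKM of the 5 mutated genes in each genotype. Each marker is 1 library (shape gives the replicate number) and each line is the mean of 3. ARID2 lies at 2.06 to 2.15 FPKM in arid2/3/4 and at 20.1 to 22.5 in WT.

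The first comparison asks which transcripts change when ARID2, ARID3 and ARID4 are mutated. ROS1, a DNA demethylase gene whose own expression depends on DNA methylation, fell from 16 ± 1.09 FPKM in WT to 1.2 ± 0.169 in arid2/3/4 (log2 fold change -2.95 ± 0.15). Of 15 seed maturation genes, 8 rose in these seedlings, and EM1, a late embryogenesis gene, went from 0.28 ± 0.217 to 42.1 ± 11.1 FPKM (5.05 ± 0.38). Members of the floral homeotic (6 of 11), jasmonate (10 of 26) and heat shock (7 of 10) lists rose, and 10 of 23 genes of light harvesting and Rubisco fell. A tandem group of genes of the lipid-transfer protein family fell: AT4G22485 by 4.23, AT4G22505 by 4.23 and AT4G22517 by 4.4 on the log2 scale. Reads may be split between such near-identical neighbours.

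Of the 31 genes for DNA methylation and RNA-directed DNA methylation (RdDM), 11 fell, 1 rose and 19 did not pass in arid2/3/4 (camera adjusted p = 0.00867). The call was lost with an estimated correlation (adjusted p = 0.59). Adjusted over the list alone, 11 fell and 2 rose. DRD1, a chromatin remodeller of RdDM, fell from 5.08 ± 0.339 to 1.36 ± 0.176 FPKM (-1.37 ± 0.13). SUVH5, a histone methyltransferase gene, fell by 1.27 and IDN2, an RNA-binding factor of RdDM, by 1.25 on the log2 scale. On the silenced reporter list of 5 genes, 2 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.384, and 0.59 with an estimated correlation). The list mixes silenced genes with others, such as ROS1, which was expressed in WT and depends on DNA methylation. Its camera test of 1 shared direction therefore does not measure silencing. The 2 that fell were ROS1 and IBM1 (-0.6 ± 0.15), and FWA rose at a low level, from 0.0218 ± 0.0191 to 0.365 ± 0.102 FPKM (0.42 ± 0.12). After quantile normalization IBM1 (-0.51) and FWA (0.3) no longer passed. IBM1 no longer passed without WT replicate 1, WT replicate 2, arid2/3/4 replicate 1 or arid2/3/4 replicate 2 (-0.66 to -0.52), and FWA no longer passed without WT replicate 1, WT replicate 2, WT replicate 3, arid2/3/4 replicate 1, arid2/3/4 replicate 2, epcr1/2 replicate 1 or epcr1/2 replicate 2 (0.35 to 0.44). With a filter at 2 FPKM the list passed (adjusted p = 0.017, range over all alternatives 0.017 to 0.928).

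Of the 14 PEAT genes, 3 fell and 11 did not pass in arid2/3/4 (camera adjusted p = 0.062; 0.59 with an estimated correlation). The 3 were the mutated genes themselves. The list passed without WT replicate 1 (adjusted p = 0.0389), with no filter (0.0353) and with a filter at 2 FPKM (0.049), in a range of 0.0353 to 0.286. Adjusted over the list alone 4 fell, and with the replicate block 7 fell. The block changed the call of HAM1 (-0.47 ± 0.14, limma adjusted p = 0.053 without it), of HAM2 (-0.33 ± 0.15, 0.156), of TRB3 (-0.44 ± 0.19, 0.146) and of PWWP2 (-0.47 ± 0.24, 0.206), which passed with it. None of these 4 passed with replicates 1 and 2 averaged as 1 sample and a batch block (-0.45 for HAM1, -0.34 for HAM2, -0.49 for TRB3 and -0.42 for PWWP2), an alternative added after the data were seen. All 4 also passed with array weights, from replicates 1 and 2 only and with a batch term, PWWP2 (-0.71) and HAM1 (-0.54) without arid2/3/4 replicate 3, and HAM1 (-0.47) with no filter and without epcr1/2 replicate 3. Of 21 histone acetylation and deacetylation genes, 2 rose and 19 did not pass (camera adjusted p = 0.817; 0.808 with an estimated correlation), and none passed adjusted over the list alone, while 3 rose and 3 fell with the block. The members that rose were HDA6, a histone deacetylase gene (0.5 ± 0.13), and YAF9B (0.68 ± 0.17). After centring (0.51) or quantile normalization (0.5), HDA6 no longer passed, nor did it without WT replicate 1, WT replicate 2, WT replicate 3, arid2/3/4 replicate 1, arid2/3/4 replicate 2, epcr1/2 replicate 1 or epcr1/2 replicate 2 (0.44 to 0.54), and YAF9B no longer passed without WT replicate 1, WT replicate 2, WT replicate 3, arid2/3/4 replicate 1 or arid2/3/4 replicate 2 (0.61 to 0.76). The median and mean of this list were negative (-0.05 and -0.02) where the direction from camera was up, and the median was 0.03 after quantile normalization.

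Of 16 tested transposable element genes (49 in the table), 1 fell and 15 did not pass in arid2/3/4 (camera adjusted p = 0.219; 0.59 with an estimated correlation). The member was DRD1, which is on the list for its description. The count was 1 adjusted over the list alone, 6 lower with the replicate block and 3 without arid2/3/4 replicate 3. AT1G64260, a MuDR family transposase gene chosen after its values were seen, is not on the list. It passed in both mutants at a low level, higher in arid2/3/4 (0.45 ± 0.1) and lower in epcr1/2 (-0.34 ± 0.1).

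Of 11 floral homeotic and meristem genes, 6 rose and 5 did not pass in arid2/3/4 (camera adjusted p = 5.62e-05), and 8 rose adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.126). AP3, a petal and stamen identity gene, went from 0.153 ± 0.105 to 3.76 ± 2.4 FPKM (1.89 ± 0.41), PI, its partner, from 0.582 ± 0.151 to 3.32 ± 1.19 FPKM (1.41 ± 0.23), and SEP3 from 5.9 ± 3.07 to 19.1 ± 2.8 FPKM (1.66 ± 0.35). AP3 no longer passed without WT replicate 2 (1.87), arid2/3/4 replicate 1 (1.56) or arid2/3/4 replicate 2 (1.7), and SEP3 without arid2/3/4 replicate 1 (1.55). Of 25 flowering time genes, 1 rose (SMZ, 0.99 ± 0.17), 1 fell (FT, -1.39 ± 0.32) and 23 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.577; 0.786 with an estimated correlation). FT no longer passed without WT replicate 1 (-1.32), WT replicate 2 (-1.08), arid2/3/4 replicate 1 (-1.39) or arid2/3/4 replicate 2 (-1.34). With the replicate block 6 flowering time genes fell and 1 rose.

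Of 15 seed maturation genes, 8 rose and 7 did not pass in arid2/3/4 (camera adjusted p = 3.02e-07), 14 rose adjusted over the list alone, and 14 rose with the replicate block. It was not called with an estimated correlation (adjusted p = 0.43). Their median log2 fold change was 4.45. SESA2, a storage albumin gene, was 242 and 230 FPKM in arid2/3/4 replicates 1 and 2 and 1.23 in replicate 3, against 0.0996 to 0.188 in WT. LEA18, a late embryogenesis gene found by size of change, rose by 4.98 ± 0.51, and AT1G68250 by 5.03 ± 0.32. Of 22 abscisic acid, cold and drought genes, 4 rose and 18 did not pass, 4 adjusted over the list alone and 8 with the block (camera adjusted p = 0.0156; 0.588 with an estimated correlation). This list no longer passed without arid2/3/4 replicate 2 (adjusted p = 0.0562) or with replicates 1 and 2 averaged and a batch block (0.0626), in a range of 2.52e-05 to 0.0626 over all alternatives. RD29B, a desiccation gene, rose by 4.39 ± 0.7.

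Of 26 jasmonate and wounding genes, 10 rose and 16 did not pass in arid2/3/4 (camera adjusted p = 4.07e-06), 13 rose adjusted over the list alone and 16 with the replicate block. This call was lost too with an estimated correlation (adjusted p = 0.126). CORI3 went from 49.2 ± 3.13 to 659 ± 232 FPKM (3.65 ± 0.45) and TAT3 from 4.35 ± 0.623 to 36.9 ± 19.7 FPKM (2.64 ± 0.43), both encoding aminotransferase family proteins. Of 10 heat shock genes, 7 rose and 3 did not pass, 8 adjusted over the list alone (camera adjusted p = 5.62e-05; 0.588 with an estimated correlation). HSP18.2, a small heat shock protein gene, rose from 4.59 ± 1.29 to 36.7 ± 11 FPKM (2.73 ± 0.26). Of 27 salicylic acid and immune genes, 3 rose and 24 did not pass, 3 adjusted over the list alone and 9 with the block (camera adjusted p = 0.0141; 0.64 with an estimated correlation). This list no longer passed without WT replicate 3 (adjusted p = 0.631), with array weights (0.121) or from replicates 1 and 2 only (0.171), in a range of 0.000647 to 0.631. EDS5, a transporter gene of salicylic acid synthesis, rose by 1.69 ± 0.26.

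Of 23 light harvesting and Rubisco genes, 10 fell and 13 did not pass in arid2/3/4 (camera adjusted p = 6.31e-06), 14 fell adjusted over the list alone and 21 with the replicate block. The call did not hold with an estimated correlation (adjusted p = 0.588). RBCS3B, a Rubisco small subunit gene, fell by 2.3 ± 0.42 and RBCS2B by 2.03 ± 0.39 on the log2 scale, though reads may be shared among these near-identical genes. Of 13 root markers, 5 fell and 8 did not pass, 5 adjusted over the list alone (camera adjusted p = 0.0219; 0.588 with an estimated correlation). The list no longer passed without WT replicate 3 (adjusted p = 0.0784), with a filter at 2 FPKM (0.086), with array weights (0.0541) or from replicates 1 and 2 only (0.0532), in a range of 0.00381 to 0.086. CASP1, which marks the endodermis, fell from 28.4 ± 3.62 to 5.77 ± 1.21 FPKM (-2.13 ± 0.18). Of 45 core histone genes, 6 fell, 2 rose and 37 did not pass, with the same counts adjusted over the list alone and 25 lower and 5 higher with the block (camera adjusted p = 0.0112; 0.59 with an estimated correlation). This list no longer passed without arid2/3/4 replicate 3 (adjusted p = 0.272) or with array weights (0.0541), in a range of 0.000273 to 0.272. AT2G37470, annotated in the histone superfamily, fell by 1.51 ± 0.22.

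Of 15 clock genes, 2 fell, 1 rose and 12 did not pass in arid2/3/4 (camera adjusted p = 0.722, and 0.786 with an estimated correlation). The counts were the same adjusted over the list alone, and 5 fell and 2 rose with the replicate block. From replicates 1 and 2 only, 6 rose and 8 fell, where 13671 of 21168 genes passed. A camera test of 1 shared direction can miss members that move both ways. RVE1 fell by 1.18 ± 0.18. Of 6 senescence genes, 0 passed with limma, over all genes or adjusted over the list alone, and 3 rose with the block (camera adjusted p = 0.529; 0.786 with an estimated correlation). SAG13 was 33.6, 35.7 and 1.46 FPKM in WT and 889, 844 and 8.71 in arid2/3/4, and passed with the block (3.73 ± 2.01, limma adjusted p = 0.232 without it) without arid2/3/4 replicate 3 (5.89), with array weights, from replicates 1 and 2 only and with a batch term, but not with replicates 1 and 2 averaged and a batch block (3.29). Of 27 genes on the cytosolic ribosomal list, 2 fell, 1 rose and 24 did not pass (camera adjusted p = 0.276; 0.786 with an estimated correlation), 0 fell and 1 rose adjusted over the list alone, and 6 fell and 1 rose with the block. The 2 that fell, RPL12-A (-1.41 ± 0.4) and RPL12-C (-1.44 ± 0.38), are described as 50S ribosomal proteins. RPL3B rose by 0.92 ± 0.17. RPL12-A no longer passed after quantile normalization (-1.29), nor did it without WT replicate 1, WT replicate 2, WT replicate 3, arid2/3/4 replicate 1, arid2/3/4 replicate 2, epcr1/2 replicate 1 or epcr1/2 replicate 2 (-1.45 to -1.28), and RPL12-C no longer passed without WT replicate 1, WT replicate 2, WT replicate 3, arid2/3/4 replicate 1 or arid2/3/4 replicate 2 (-1.52 to -1.33).

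By limma, 4399 of 21168 genes changed in arid2/3/4 against WT, 1859 higher and 2540 lower, and 9545 changed with the replicate block. The count was 2361 without WT replicate 1, 2485 without WT replicate 2, 2206 without arid2/3/4 replicate 1, 2169 without arid2/3/4 replicate 2 and 7064 without arid2/3/4 replicate 3. With replicates 1 and 2 averaged as 1 sample and a batch block, an alternative added after the data were seen, it was 2003. Of the genes given for arid2/3/4, the calls of ARID3, SESA2, GER3, AT1G07500, IBM1, FWA, YAF9B, HDA6, FT, AP3, PI, SEP3, RD29B, RBCS3B, RBCS2B, RPL12-A and RPL12-C ended in that fit. From only the groups compared, IBM1, FWA, YAF9B, HDA6 and SESA2 no longer passed, and with no filter RPL12-A and SESA2 did not. SESA2 also failed after quantile normalization and without any 1 library other than arid2/3/4 replicate 3. The 3 mutant and 3 WT libraries did not overlap in 37.2% of genes, where chance gives 10% if all 6 are independent. With replicates 1 and 2 averaged as 1 sample the share was 43.4%, where chance gives 33.3% if replicate 3 carries no shift of its own. The genotypes share such a shift, which makes overlap more likely, so the share by chance should be lower.

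**Figure D2:**
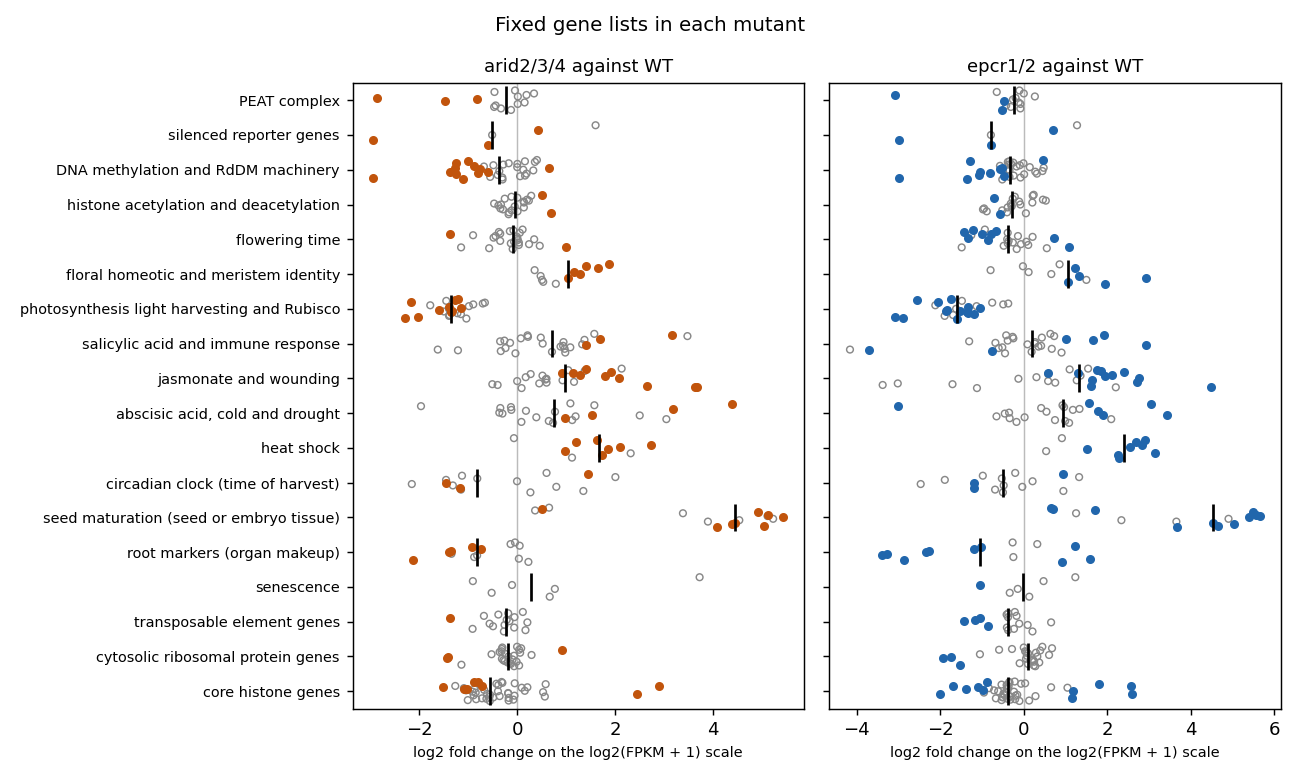
Log2 fold change, on the log2(FPKM + 1) scale, of every tested member of the 18 fixed lists in arid2/3/4 (left) and epcr1/2 (right) against WT. Each point is 1 gene, filled where its limma adjusted p was under 0.05, and the black line is the list's median. The seed maturation list has medians of 4.45 and 4.53.

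The second comparison asks the same of EPCR1 and EPCR2. ROS1 fell to 1.16 ± 0.307 FPKM in epcr1/2 (log2 fold change -2.99 ± 0.15, limma adjusted p = 3.96e-05). STM, which maintains the shoot meristem, rose from 3.24 ± 1.09 to 32 ± 11 FPKM (2.93 ± 0.3), and KNAT6, of the same homeobox family, from 4.34 ± 0.93 to 20.3 ± 7.7 FPKM (1.94 ± 0.29). SVP and FLM, genes of floral repressors, fell. CRA1, a seed storage protein gene, rose from 0.415 ± 0.0919 to 67.2 ± 26.9 FPKM (5.5 ± 1.09). The root iron transporter gene IRT1 fell from 12.1 ± 2.41 to 0.258 ± 0.312 FPKM (-3.39 ± 0.41), and the germin gene GER3 from 824 ± 444 to 9.95 ± 6.35 FPKM (-6.19 ± 0.73).

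Of 31 DNA methylation and RdDM genes, 9 fell, 1 rose and 21 did not pass in epcr1/2, the same adjusted over the list alone, and 15 fell and 2 rose with the replicate block (camera adjusted p = 0.0545; 0.653 with an estimated correlation). The list passed without WT replicate 1 (adjusted p = 0.0468), WT replicate 2 (0.0297), arid2/3/4 replicate 3 (0.0426) or epcr1/2 replicate 2 (0.0492), with no filter (0.0321) and from only the groups compared (0.0432), in a range of 0.0297 to 0.181. NRPE1, the largest subunit of RNA polymerase V, fell from 3.66 ± 0.461 to 0.917 ± 0.148 FPKM (-1.28 ± 0.18), and the demethylase gene DML2 by 1.36 ± 0.15. On the silenced reporter list of 5 genes, which mixes silenced genes with others such as ROS1, 2 fell and 1 rose, as adjusted over the list alone. Its camera test (adjusted p = 0.475, and 0.648 with an estimated correlation) therefore does not measure silencing. IBM1 fell by 0.79 ± 0.15 and FWA rose by 0.69 ± 0.12. With a filter at 2 FPKM the list passed (adjusted p = 0.0208, range 0.0208 to 0.665). Of 16 tested transposable element genes, 4 fell and 12 did not pass, also adjusted over the list alone, and 8 fell and 1 rose with the block (camera adjusted p = 0.169; 0.59 with an estimated correlation). They were AT2G38695, a retrotransposon-related gene (-1.43 ± 0.3), AT3G13030, of a hAT transposon family (-0.87 ± 0.22), and ADC1 and DRD1, listed for their descriptions. AT3G13030 no longer passed without WT replicate 1, WT replicate 2, WT replicate 3, epcr1/2 replicate 1 or epcr1/2 replicate 2 (-0.92 to -0.76).

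Of 14 PEAT genes, 3 fell and 11 did not pass in epcr1/2, 2 fell adjusted over the list alone, and 5 fell with the replicate block (camera adjusted p = 0.114; 0.64 with an estimated correlation). Besides EPCR1 these were ARID4 (-0.48 ± 0.15, limma adjusted p = 0.0454) and UBP5, a ubiquitin protease gene (-0.53 ± 0.14, limma adjusted p = 0.026), and both no longer passed after centring (-0.37 and -0.41) or quantile normalization (-0.32 and -0.34). ARID4 no longer passed without WT replicate 1, WT replicate 2, WT replicate 3, arid2/3/4 replicate 1, arid2/3/4 replicate 2, epcr1/2 replicate 1, epcr1/2 replicate 2 or epcr1/2 replicate 3 (-0.54 to -0.39), and UBP5 no longer passed without WT replicate 1, WT replicate 2, WT replicate 3, epcr1/2 replicate 1 or epcr1/2 replicate 3 (-0.56 to -0.47). PWWP2 (-0.65 ± 0.24, limma adjusted p = 0.0769) and TRB3 (-0.42 ± 0.19, 0.145) passed with the block, with array weights, from replicates 1 and 2 only and with a batch term, and PWWP2 (-0.65) also without arid2/3/4 replicate 3 and from only the groups compared, but neither passed with replicates 1 and 2 averaged and a batch block (-0.7 and -0.42). Of 21 histone acetylation and deacetylation genes, 2 fell and 19 did not pass, 2 adjusted over the list alone, and 7 fell and 3 rose with the block (camera adjusted p = 0.419; 0.59 with an estimated correlation). They were the deacetylase gene HDA5 (-0.72 ± 0.16) and SWC4 (-0.57 ± 0.13). HDA5 no longer passed without WT replicate 1, epcr1/2 replicate 1 or epcr1/2 replicate 2 (-0.7 to -0.63), and SWC4 no longer passed without WT replicate 1, epcr1/2 replicate 1 or epcr1/2 replicate 2 (-0.57 to -0.5).

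Of 25 flowering time genes, 7 fell, 2 rose and 16 did not pass in epcr1/2, 8 fell and 2 rose adjusted over the list alone, and 12 fell and 3 rose with the replicate block (camera adjusted p = 0.219; 0.653 with an estimated correlation). SVP fell from 47.7 ± 1.74 to 18.4 ± 1.7 FPKM (-1.33 ± 0.17), FLM by 1.21 ± 0.18 and MAF3 by 1.44 ± 0.32. SMZ, another floral repressor gene, rose by 1.08 ± 0.17. Of 11 floral homeotic and meristem genes, 5 rose and 6 did not pass, 6 rose adjusted over the list alone, and 7 rose and 1 fell with the replicate block (camera adjusted p = 0.000808). With an estimated correlation the adjusted p = 0.126. WUS, a stem cell gene of the shoot meristem, went from 0, 0.0423 and 0 FPKM in WT to 1.72, 2.19 and 0.888 in epcr1/2 (1.32 ± 0.21).

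Of 15 seed maturation genes, 11 rose and 4 did not pass in epcr1/2, and 13 rose adjusted over the list alone (camera adjusted p = 3.02e-07). With an estimated correlation the adjusted p = 0.43. Of 22 abscisic acid, cold and drought genes, 5 rose, 1 fell and 16 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0153; 0.588 with an estimated correlation), and this list no longer passed after quantile normalization (adjusted p = 0.0588) or with replicates 1 and 2 averaged and a batch block (0.0626), in a range of 9.47e-05 to 0.0626. RD22 rose by 1.89 ± 0.31. Of 26 jasmonate genes, 12 rose and 14 did not pass, 14 adjusted over the list alone, and 18 rose and 1 fell with the replicate block (camera adjusted p = 2.65e-06). With an estimated correlation the adjusted p = 0.126. CORI3 rose to 1280 ± 840 FPKM (4.48 ± 0.45), and JAZ10, a repressor gene of jasmonate signalling, by 2.72 ± 0.54. Of 10 heat shock genes, 8 rose and 2 did not pass, 8 adjusted over the list alone (camera adjusted p = 2.65e-06; 0.588 with an estimated correlation). HSP17.6A rose by 2.9 ± 0.32. Of 27 salicylic acid and immune genes, 4 rose, 2 fell and 21 did not pass, 3 and 2 adjusted over the list alone (camera adjusted p = 0.361; 0.786 with an estimated correlation), with a median of 0.19 and a mean of -0.04. From replicates 1 and 2 only, 6 rose and 16 fell, and the list's direction turned to down without passing (camera adjusted p = 0.184). WRKY18, a transcription factor gene, rose by 2.92 ± 0.33.

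Of 23 light harvesting and Rubisco genes, 14 fell and 9 did not pass in epcr1/2, and 17 fell adjusted over the list alone (camera adjusted p = 2.68e-05; 0.588 with an estimated correlation). RBCS2B fell by 3.1 ± 0.39 and LHCB1.2, a chlorophyll-binding protein gene, by 2.56 ± 0.37 on the log2 scale, both with near-identical relatives. Of 13 root markers, 7 fell, 3 rose and 3 did not pass, also adjusted over the list alone (camera adjusted p = 0.157; 0.59 with an estimated correlation). With no filter the list passed (adjusted p = 0.0353, range 0.0353 to 0.422). CASP1 fell by 2.86 ± 0.18 and EXPA18, a root hair gene, by 2.35 ± 0.32. Of 45 core histone genes, 6 fell, 5 rose and 34 did not pass, also adjusted over the list alone, and 20 fell and 7 rose with the replicate block (camera adjusted p = 0.384; 0.786 with an estimated correlation). AT1G13370, of the histone superfamily, rose by 1.81 ± 0.21.

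Of 15 clock genes, 2 fell, 1 rose and 12 did not pass in epcr1/2 (camera adjusted p = 0.714, and 0.786 with an estimated correlation). Adjusted over the list alone 1 fell and 0 rose, and 4 fell and 1 rose with the block. From replicates 1 and 2 only, 4 rose and 7 fell, where 13755 of 21168 genes passed. Here too the camera test can miss members that move both ways. RVE1 fell by 1.18 ± 0.18. Of 6 senescence genes, 1 fell, NAC092 (-1.05 ± 0.29), also adjusted over the list alone, and 5 did not pass (camera adjusted p = 0.979; 0.987 with an estimated correlation). The list's median was -0.01 and its mean 0.05, and the median was 0.09 after quantile normalization. NAC092 no longer passed after centring (-0.94) or quantile normalization (-0.88), nor did it without WT replicate 1, WT replicate 2, WT replicate 3, epcr1/2 replicate 1 or epcr1/2 replicate 3 (-1.12 to -0.81). Of 27 genes on the cytosolic ribosomal list, 3 fell and 24 did not pass, also adjusted over the list alone, and 5 fell and 3 rose with the block (camera adjusted p = 0.384; 0.786 with an estimated correlation). The median was 0.1 and the mean -0.09. The 3 were RPL12-C (-1.93 ± 0.38), RPL12-A (-1.74 ± 0.4) and RPL27 (-1.52 ± 0.36), the first pair described as 50S ribosomal proteins and RPL27 placed in the chloroplast by its annotation, so none of the 3 stands for the cytosolic ribosome. RPL12-A no longer passed without WT replicate 2, epcr1/2 replicate 1 or epcr1/2 replicate 2 (-1.66 to -1.49), and RPL27 no longer passed without epcr1/2 replicate 1 or epcr1/2 replicate 2 (-1.32 to -1.31).

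By limma, 6039 genes changed in epcr1/2 against WT, 2277 higher and 3762 lower, and 10832 changed with the replicate block. The count was 3948 without WT replicate 1, 3731 without epcr1/2 replicate 1 and 3708 without epcr1/2 replicate 2. Averaging replicates 1 and 2 as 1 sample with a batch block, added after the data were seen, gave 4814. In that fit the calls of ARID4, UBP5, SWC4, WUS, RD22, AT3G13030, AT1G07500, RPL12-A, RPL12-C and RPL27 ended. ARID4 also no longer passed with no filter or from only the groups compared. Of the changed genes 37.7% were higher, and 45.9% after centring or 46.7% after quantile normalization. The median log2 fold change of all tested genes was -0.119, and -0.003 after centring and 0.005 after quantile normalization. The 3 mutant and 3 WT libraries did not overlap in 46.6% of genes (10% by chance if all are independent). The share was 53.2% with replicates 1 and 2 averaged (33.3% by chance if replicate 3 carried no shared shift, and lower with it).

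**Figure D3:**
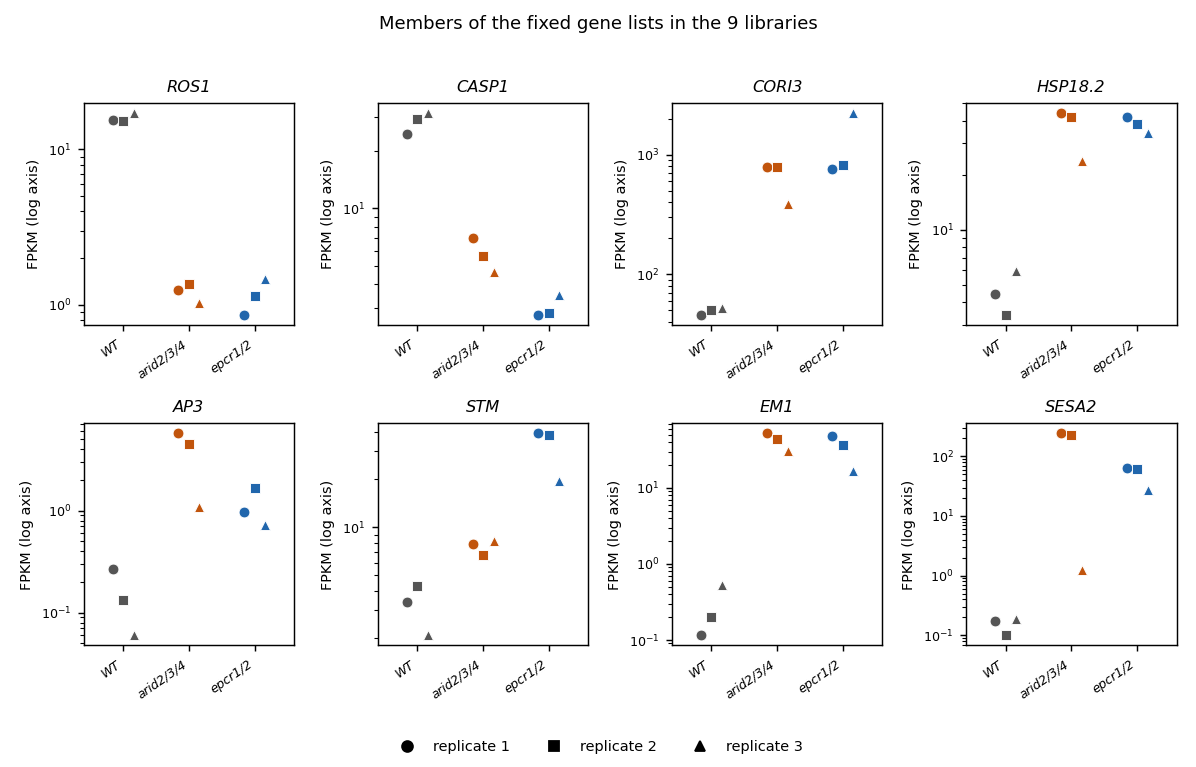
FPKM on a log axis of 8 members of the fixed lists, chosen for the plot after their values were seen. Each marker is 1 library and its shape gives the replicate number. ROS1 lies at 15.2 to 17.2 FPKM in WT and at 0.859 to 1.47 in the mutants, and SESA2 in arid2/3/4 replicate 3 lies at 1.23 FPKM, far below replicates 1 and 2.

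The overlap asks whether the mutants share their changes. Of the tested genes, 1121 were higher in both mutants and 1764 lower in both, 2885 in all, and 53 went in opposite directions. LEA18 rose by 4.98 and 5.49, AT1G68250 by 5.03 and 5.43, and GER3 changed by -4.31 and -6.19 in arid2/3/4 and epcr1/2. AT1G07500 was listed at 0, 0 and 8.35 FPKM in WT, 592, 561 and 111 in arid2/3/4 and 154, 106 and 38.9 in epcr1/2. Across genes the log2 fold changes had Pearson r = 0.771 and a covariance of 0.603. Simulated unchanged groups sharing the WT libraries gave a mean r of 0.501 (highest 0.549), a mean covariance of 0.125 and at most 1 gene in the same direction. That simulation leaves out the shift of replicate 3 that the genotypes share. In 100 more, added after the data were seen, with this shift and with replicates 1 and 2 as 1 sample, the mean r was 0.496 (highest 0.53), the mean covariance 0.073 and the genes in the same direction at most 3. No gene changed in either simulation, so almost none could be called, and their low counts do not test sharing. The covariance exceeded the simulated ones by 0.478 and 0.53. Independent lists of these sizes would share 200 higher and 451 lower genes. The simulations already hold the sharing of the WT libraries, and the independent lists do not, so sharing may explain part of the excess over those lists. The 3 WT libraries could not be split into parts of at least 2. A deviation of WT beyond the simulated spread was therefore not tested. With the replicate block 6406 genes changed in the same direction, and 1356 with replicates 1 and 2 averaged and a batch block. The count was 1490 without WT replicate 1, 1597 without WT replicate 2, 1545 without arid2/3/4 replicate 1, 1517 without arid2/3/4 replicate 2 and 4353 without arid2/3/4 replicate 3.

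The third comparison tests the difference between the mutants themselves. AGO5, an Argonaute gene, was 26.6 ± 10.1 FPKM in arid2/3/4 and 0.349 ± 0.0829 in epcr1/2 (log2 fold change 4.3 ± 0.24, limma adjusted p = 0.000133), against 0.117 ± 0.142 in WT. AT1G12010, of the 2-oxoglutarate-dependent oxygenase family, was 2.94 ± 0.75 in arid2/3/4 and 106 ± 2 in epcr1/2 (-4.77 ± 0.16, limma adjusted p = 3.34e-05). AT1G20070 was 15 ± 3.48 and 304 ± 17.8 FPKM (-4.27 ± 0.24), and AT4G29570, of the cytidine deaminase family, 1.29 ± 0.811 and 35.7 ± 11.2 FPKM (-4.02 ± 0.36). AT2G36815 was listed at 0, 0 and 1.29 FPKM in arid2/3/4 and at 31.8, 35.2 and 36.6 in epcr1/2. AT2G30766 was higher in arid2/3/4 by 4.94 ± 0.56. ARID3 differed by -0.57 ± 0.16 (limma adjusted p = 0.0599) and passed with the replicate block, with array weights, from replicates 1 and 2 only, with a batch term, without arid2/3/4 replicate 3 (-0.72), after centring (-0.67) and after quantile normalization (-0.65), but not with replicates 1 and 2 averaged and a batch block (-0.49).

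By limma, 2218 genes differed between the mutants, 1208 higher and 1010 lower in arid2/3/4, and 6039 with the replicate block. The share higher in arid2/3/4 was 54.5%, and 40.8% after centring or 42.8% after quantile normalization. The count was 870 without arid2/3/4 replicate 1, 1007 without arid2/3/4 replicate 2, 843 without epcr1/2 replicate 1 and 834 without epcr1/2 replicate 2. With replicates 1 and 2 averaged as 1 sample and a batch block, added after the data were seen, it was 49, and the call of AT2G30766 ended. The libraries of the mutants did not overlap in 30.3% of genes (10% by chance if all are independent), and in 36.7% with replicates 1 and 2 averaged. The 33.3% by chance leaves out the shift of replicate 3 that the genotypes share and is too high. Closeness to it therefore does not show that the mutants are alike. Of 11396 genes called between the mutants from replicates 1 and 2 only, 79.4% kept their direction in replicate 3.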

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

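No test in this part was chosen after the result was seen.

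In all, 53 genes passed the test in both mutants in opposite directions. A difference between the mutants follows from opposite calls against the same WT libraries and adds no support. Of these, 30 were higher in arid2/3/4 and lower in epcr1/2, and 23 were lower in arid2/3/4 and higher in epcr1/2. AT1G12010 had log2 fold changes of -1.33 in arid2/3/4 and 3.44 in epcr1/2, and GAMMA-TIP, a water channel gene of the vacuole, -1.28 and 2.46. NRPE3B, a gene of the RNA polymerase family, had 1.44 and -1.19. These 3 were chosen after their values were seen. With the replicate block, 246 genes went in opposite directions. No explanation was tested for these genes.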

How the results depend on the processing

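Tests of replicates 1 and 2 only, the batch term, the averaged replicates, genes above 0 in all libraries and product names only were chosen after the data were seen.

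No list test or result for a named gene that passed in either fit turned its direction under an alternative, but the balance between the mutants turned to more genes lower in arid2/3/4 after centring and after quantile normalization. Of the 36 list tests at the preset correlation, 26 kept their side of the threshold under all alternatives run for lists and 10 did not. The 2-fold minimum was not run for lists. The estimated correlation, with which no list passed, is not counted among these alternatives. Of 198 results for named genes, 91 kept their side and 107 did not. Without passing in either fit, 4 list tests and 11 results for named genes turned direction somewhere. Among them was the histone acetylation list in arid2/3/4 with replicates 1 and 2 only. At the preset correlation, 22 list tests kept both direction and side, as did 81 results for named genes. The replicate block changed the calls of 8 results for named genes, given with the results, and of no list or other named gene, and none of these 8 passed with replicates 1 and 2 averaged and a batch block. In the order arid2/3/4, epcr1/2, mutants against each other and overlap, the counts were 4399, 6039, 2218 and 2885. With the replicate block they were 9545, 10832, 6039 and 6406, with robust fitting and array weights 13934, 14627, 12494 and 9877, with a 2-fold minimum 2434, 3563, 1111 and 1546. With replicates 1 and 2 only they were 13671, 13755, 11396 and 9463, and with the batch term 10595, 11685, 7338 and 7225. With replicates 1 and 2 averaged and a batch block, arid2/3/4 had 2003, epcr1/2 4814, the mutants 49, the overlap 1356 and named genes 90 in place of 163, from fewer samples, and 73 calls of named genes ended. With only the groups compared, the mutants had 1477.

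Transposable element genes in arid2/3/4 (1) and epcr1/2 (4) were 7 and 9 with array weights, 6 and 9 with the replicate block and 6 and 9 with the batch term. By product name only they were 0 and 2, from a list of 8 tested genes, and for arid2/3/4 they were 2 with no filter and 8 with replicates 1 and 2 only. The array weights of the libraries numbered 3 were 0.085 to 0.128, so that fit rests on the others. Where no construction shows it, the cause was not tested.

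Leaving out 1 library gave 2169 to 7064 genes in arid2/3/4, 3708 to 7575 in epcr1/2, 834 to 3284 between the mutants and 1490 to 4353 in the overlap. The transposable element counts ranged from 1 to 3 and from 3 to 4, the passing lists from 14 to 18 (16 with all libraries) and the passing named genes from 114 to 167. The libraries that moved a count most stand beside it in the results. Depth is known only roughly. At this spread 23 of 100 simulated 2-fold changes were called, so changes of that size can be missed. The simulation changed 200 genes, and far more were called in the data, which loosens the adjusted threshold. The share missed in these comparisons is therefore not known.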

Other observations

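All tests in this part except those of flower tissue and of other splits of the libraries were chosen after the result was seen.

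SDC, a silenced F-box gene, was 0.026, 0.0299 and 0.596 FPKM in WT, 0.613, 0.614 and 17.1 in arid2/3/4 and 0.608, 0.167 and 11.7 in epcr1/2. Within each replicate number SDC was higher in both mutants than in WT, though it did not pass the test in either. The libraries numbered 3 differed from the others in SDC, and also in other genes, chosen after their values were seen. The clock gene ELF4 was 139, 130 and 1.6 FPKM in WT, 18.8, 20.3 and 0.275 in arid2/3/4 and 8.85, 9.32 and 1.76 in epcr1/2. The immune gene PR1 was 592, 666 and 1.67 in WT, 756, 752 and 48.2 in arid2/3/4 and 196, 181 and 110 in epcr1/2, so its gap was far smaller there. In all, 105 genes were under 0.01 FPKM in every replicate 1 and 2 and at 10 or more in every replicate 3, with a median transcript length of 111 bases against 1687 for tested genes. MT1A was 0 in all replicates 1 and 2 and 13600, 9880 and 16500 FPKM in the replicates numbered 3. Whether such zeros are failed estimates was not tested.

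The library numbered 3 stood apart in every genotype. Against counting noise as the whole cause, the spread at 1000 FPKM or more was at least 1.83 times that at 10 to 20 FPKM, where counting noise would fall, and against transcript length, removing its trend left 0.62 of 0.71 in WT, 0.88 of 0.89 in arid2/3/4 and 0.75 of 0.78 in epcr1/2, at least 4.8 times the spread between replicates 1 and 2. Clock genes differed more than matched random lists in WT (percentile 100), which is consistent with another time of harvest there, but lay at percentile 72.2 in arid2/3/4 and 9.8 in epcr1/2, which leaves it open. The bounds, the 95th and 5th percentiles, were set with these percentiles known, after a single test over the genotypes had been undecided, and a first lower bound, the middle of the random lists, would have counted against harvest time in epcr1/2. A batch of plants or libraries stays open, as the labels name none, as do other effects of depth, since a spread at least 26.4 times the counting error can arise from any difference between samples, and no biological explanation was tested.

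Of 15 seed maturation genes, 8 were higher in arid2/3/4 and 11 in epcr1/2, and the list was not called with an estimated correlation (adjusted p = 0.43). Against scaling as the cause, the median log2 level of genes at 5 FPKM or more differed little between libraries (4.442 to 4.68). The list's medians after quantile normalization, 4.35 in arid2/3/4 and 4.53 in epcr1/2, could therefore hardly have come out low and add no test. The log2 ratio of storage protein to EM1 and EM6 transcripts ranged by 0.3 over the epcr1/2 libraries, which is consistent with seeds or embryos in the sample and equally with a seed programme active in seedlings. In arid2/3/4 it ranged by 6.2, because storage transcripts summed to 1260, 1190 and 9.5 FPKM, and since this rests on replicate 3 the explanations cannot be told apart. The genotype itself stays among the open explanations.

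Of 11 floral and meristem genes, 6 were higher in arid2/3/4 and 5 in epcr1/2, and the list was not called with an estimated correlation (adjusted p = 0.126). Of 14 anther, pollen and petal genes, 0 reached a mean of 1 FPKM in either mutant and 1 (QRT3) did in WT. This argues against flower tissue in an amount that brings most of these genes to 1 FPKM. AP3 and PI were themselves low in arid2/3/4, so the cutoff cannot exclude a trace of flower tissue. Some markers were higher in a mutant (MYB21, mean 0.09 FPKM in WT and 0.532 in epcr1/2). Others were lower (QRT3, 1.107 and 0.844). Floral tissue too young to express the markers was not tested and stays open. After quantile normalization the lower of the list's medians was 1.14, but library levels differed too little for this to test scaling. A changed share of organs, such as less root, was not tested and stays open, as 5 of 13 root markers fell in arid2/3/4, and 7 fell and 3 rose in epcr1/2. A change of expression within organs stays open too. Other technical causes, such as the unlabelled batch, were not excluded.

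Genes at least 2-fold higher may lie next to each other. Among tested genes in chromosome order, epcr1/2 had 130 adjacent pairs of unlike product, against a mean of 87.3 and a highest of 120 in 10000 shuffles. In arid2/3/4 the number was 76, against a mean of 51.7 and a highest of 80, which did not exceed every shuffle as the test required. Neighbouring genes share expression for many reasons and overlapping transcripts were not removed, so this says nothing of heterochromatin.

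Splits of the 6 libraries of a comparison number 10, the real one included, too few for a share under 0.05. In arid2/3/4 against WT, 1 split, the real one, gave 4399 genes and the highest other 0. The same held for epcr1/2 with 6039 and 0, and for the mutants with 2218 and 0. The 3 other splits that part all 3 replicate pairs also gave 0, and differ in mixing the genotypes. For transposable element genes the real splits gave 1 and 4 and the highest other 0. For the overlap, 1 of 100 splits of the 9 libraries that were run, the real one, gave as many as 2885 genes, but most of these splits put libraries of the same number together. The highest other gave 2379, and in it the group in the place of WT was the 3 libraries numbered 3, which points to a structure of the samples. Only 14 of the 100, the real one included, kept 1 library of each number in each group, too few for a share under 0.05. Of these the highest other was 741, with the genotypes intact and arid2/3/4 in the place of WT, and the highest that mixed genotypes was 119.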
